A study of Mus musculus with 12 samples.

How the data were processed

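Chromatin accessibility was measured by ATAC-seq in mouse CD4 T cells sorted in 6 groups of 2 libraries, 12 in all. Each library came with 1 deposited peak list. Per the submitters' processing notes, Bowtie2 2.3.3, HOMER 4.10 and bedtools were used with the mm10 build; their roles, order and settings are not given in the sources used here, nor is the way reads were shifted for the transposase or how many reads lie behind a list. The names of the deposited lists speak of an intersection, and what was intersected is not given in the sources used here. Each list has 5 columns: chromosome, start, end, a name and a score. The score deposited by the authors is 1000 for every peak in every library, so it cannot rank peaks and was not used further. The deposited coordinates are the measurement; no signal height was analysed here. No peak is narrower than 150 bp.

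Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates come from separate animals, so p-values from comparing libraries measure only the spread between these samples, which may be technical; those of gene lists measure the spread between genes. Library names carry 2 run codes, BW13 for the converted donor, unconverted donor and host conventional libraries and DR31 for the host regulatory libraries, and no code for the libraries induced in culture. Comparisons across codes therefore cannot be told apart from the run. The numbers in the library names also differ between groups, from 9859 to 50000. They ran from 9859 to 17000 in the in vivo regulatory libraries. In the conventional libraries and those induced in culture they ran from 42000 to 50000. Differences between in vivo regulatory and conventional libraries therefore cannot be told apart from this number. Replicate numbers in titles and in descriptions differ for some groups, and nothing in the labels ties equal numbers to 1 animal or day.

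Peaks of all libraries that shared at least 1 bp were merged into 76882 consensus regions, and a library carried a region if it had a peak there. Genes came from a RefSeq table of the GRCm38.p6 assembly, which shares its coordinates with mm10. That table gives start and end without strand, so distances were taken to the nearest end of a protein-coding gene in place of the transcription start that had been planned. Of the regions, 16.6% lay within 1 kb of a gene end, against 5.73% after a shift by 10 kb and 5.49% after a shift by 100 kb. A region was assigned to the gene whose body held its midpoint, else to the gene with the nearest end within 50 kb; 89.9% were assigned. All 267 genes of the lists were found in the table, 1 of them through an older symbol. Coordinates are given from 1.

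For each of 7 comparisons of 2 groups, regions were counted that had a peak in both libraries of one group and in neither of the other. With 2 libraries against 2 a test per region cannot go below 1 in 3, so no p is given. The count is set beside the counts from the 2 other splits of the same 4 libraries. Those splits measure replicate spread only at regions where the replicates of both groups differ, and leave out regions where those of a single group do. Regulatory and conventional libraries, 8 against 4, were compared by a two-sided Fisher's exact test per region with Benjamini-Hochberg adjustment at 0.05 over the regions that could reach an unadjusted p under 0.05. Gene lists were tested by a two-sided permutation test with 100000 random lists matched on the number of regions per gene, adjusted over all 152 list tests. Similarity was tested by a one-sided exact permutation test of the Jaccard index over pairings within run code. Regions of the host and cultured regulatory groups were followed in the BW13 libraries by a two-sided exact permutation test over 15 splits. The 19 lists covered Treg core, effector and tissue Treg, naive and quiescence, Th1 and cytotoxic, Th2, Th17, Tfh, anergy and exhaustion, TCR activation, TGF-beta, bone marrow homing and retention, pan-T and CD4 lineage, and CD8 T, NK, B, plasma, myeloid, erythroid and stem and progenitor cells; they were written from general knowledge. The lists, the tests and the alternatives were fixed before the data were examined, except where stated.

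Genes are named by a rule also fixed beforehand. In each comparison of 2 groups these are the 10 genes with the largest net number of regions in each direction, among those whose net number exceeds that of both other splits, with ties going to the gene with fewer regions. For regulatory against conventional libraries they are the 10 genes with most regions past the threshold in each direction. The 26 fixed genes were looked at in every comparison of 2 groups, and those with equal numbers in both directions are mostly left out of the text; some items are not reported here. Il2ra, Ctla4 and Nrp1 encode proteins used in the sorts, and LAP is the propeptide of the Tgfb1 product, so their regions are not findings between groups sorted on them. Other genes are named only where said to be chosen after their values were seen.

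Since the lists differ in length, each count was repeated with the 28394 widest peaks of every library. This replaced the planned ranking by score, was chosen after seeing the data, and rests on width, which is not signal. Further repeats used fixed windows of 500 bp, autosomes only, leaving out each library, the replicate number as a block, base-pair overlap and other rules for regions and genes. The planned motif comparison was not run, as it needs genome sequence that is not used here. The steps were run on simulated data with libraries drawn independently, without group or run structure. For regulatory against conventional libraries, 2000 changed regions among 76882 were set in all libraries of one kind and none of the other. That 100% of them were called follows from this setting and does not measure power in the real libraries. In the same setting 0.6% of calls were not among them, and 1% of 200 unchanged random lists had a p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.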

Results

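T cells with a transgenic receptor for the influenza hemagglutinin (6.5TCR) were transferred into Aire-HA mice, and T cell subsets of the bone marrow were sorted 14 days later to compare their open chromatin. The donor cells were split into those not converted to regulatory T cells (donor Tconv, CD25 negative) and those that were (donor Treg, positive for CD25 and for LAP, the latent TGF-beta peptide). Host cells were sorted as conventional (host Tconv, CD25 negative) and as regulatory cells without or with Nrp1 (host pTreg and host tTreg, positive for CD25 and CTLA4). Regulatory cells induced in culture (iTreg) were the remaining group. Each group had 2 libraries.

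The lists held 496365 peaks. Peak numbers were 45771.5 ± 2010 (SD, n = 2) in donor Tconv, 33350.5 ± 1579 in donor Treg, 40757.5 ± 5243 in host Tconv, 60782 ± 3429 in iTreg, 35409.5 ± 3570 in host pTreg and 32111.5 ± 5257 in host tTreg. Of 76882 consensus regions, 21435 (27.9%) had a peak in all 12 libraries and 11433 in 1 library. Regions open in all libraries lay near genes more often, 40.2% within 1 kb of a gene end against 7.5% of the rest. The read depth behind the lists is unknown, so a missing peak is not evidence of closed chromatin.

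Peak sets of 2 libraries of 1 group were on average closer than those of different groups, and the in vivo regulatory groups lay close to each other. The Jaccard index of the 2 libraries of a group was 0.856 in donor Tconv, 0.84 in donor Treg, 0.833 in iTreg, 0.803 in host pTreg, 0.773 in host Tconv and 0.746 in host tTreg. Donor Treg reached a mean of 0.779 with host pTreg and 0.771 with host tTreg, but 0.633 with donor Tconv, 0.647 with host Tconv and 0.463 with iTreg. Lists of unlike length lower the index. With equal list lengths the means were 0.794 with host pTreg, 0.803 with host tTreg, 0.698 with donor Tconv, 0.684 with host Tconv and 0.59 with iTreg. The gaps thus narrowed, and host pTreg and tTreg changed order. Donor Tconv and host Tconv reached 0.789, above the index of the host Tconv pair itself. The mean over same-group pairs was 0.808 against 0.71 for pairs of other groups with the same run code (one-sided exact permutation test, p = 0.0444, 2 of 45 pairings). With equal list lengths the same-group mean was 0.843 and the exact permutation p was 0.0222. With overlap counted in base pairs the mean was 0.754 and the exact permutation p was 0.111, so the call rests on the measure. The exact permutation p was 0.133 and 0.111 without donor Tconv replicates 1 and 2, 0.0889 without host Tconv replicate 1, and 0.111 and 0.0667 without host pTreg replicates 1 and 2.

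**Figure D1:**
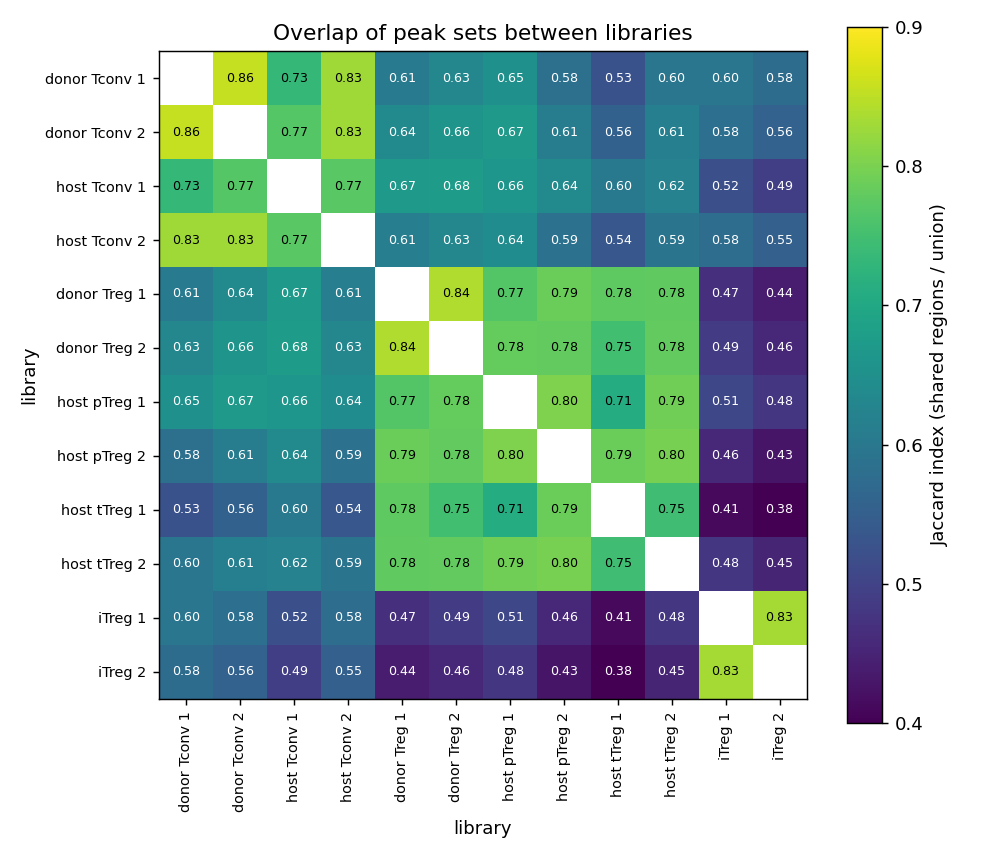
Jaccard index (shared regions over the union of regions) of each pair of the 12 libraries, with libraries on both axes and the diagonal left blank. Donor Treg libraries average 0.779 with host pTreg and 0.463 with iTreg. All peaks are used, and with equal list lengths these means are 0.794 and 0.59.

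Converted and unconverted donor cells, which share origin and receptor, differed at regions of regulatory T cell genes. Ikzf2, which encodes the regulatory T cell transcription factor Helios, had 6 regions with a peak in both donor Treg libraries and neither donor Tconv library, and 2 in reverse. Lrrc32, whose product GARP presents latent TGF-beta, had 3 and 0, Itgae (CD103) 3 and 0, and Itgb8, a subunit of an integrin that activates latent TGF-beta, 4 and 0. Genes of naive T cells were mixed. Lef1 had 0 and 7 of 20 regions, Satb1 0 and 6 of 16, Bach2 2 and 10 of 44 and Foxp1 4 and 23 of 69. Tcf7 and Il7r had 0 and 0 and Ccr7 1 and 0. Over the whole genome the numbers were 1230 and 10132 of 50938, so regions in donor Tconv only were common at any gene with many regions. Il2ra, which encodes the sorted CD25, had 3 and 0, and Ctla4 1 and 3.

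Further genes with most regions in donor Treg were Rad51b (8 and 2), Emsy (6 and 1), which lies beside Lrrc32 on chromosome 7, Plcl1, Lamc1 and Atxn1 (5 and 0 each), Hdac9 and Cwc27 (5 and 1 each), and Sgip1 and Samsn1 (4 and 0 each). In donor Tconv, Tgfbr3, a TGF-beta co-receptor gene, had 14 and none in donor Treg. Khdrbs3, Cox10, Chd7 and Maml2 had 13 each, and Myo10, Tbc1d22a, Atp10a and Chn2 had 12 each. The Th1 factor gene Tbx21 had 0 in donor Treg and 3 in donor Tconv. Lag3, Nrp1 and Tgfb1 had 0 and 1 each, Ikzf4 and Pdcd1 1 and 0 each, and Icos and Prdm1 1 and 1 each. With lists of equal length the net turned to donor Treg at Ctla4 (3), Tbx21 (1) and Lag3 (1).

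As a group, the Treg core list had 24 regions in donor Treg only and 17 in donor Tconv only, a net of 7 against -30.5 in matched random lists (permutation test, adjusted p = 0.00051). Of its 20 genes, 8 had a net excess in donor Treg and 8 in donor Tconv. The effector and tissue Treg list had 23 and 12 (random net -28.4, permutation test, adjusted p = 0.00051). Without Il2ra, Ctla4 and Nrp1, an alternative chosen after seeing the data, the Treg core list kept a net of 7 against -22.5 (permutation p = 2e-05, the smallest the permutations can give). Lrrc32 stayed in that list, although its product presents the latent TGF-beta that the donor sort detects through LAP. The list is therefore not free of genes tied to the sort. Per 10000 regions with a peak, Treg core regions numbered 40.9 and 40.7 in the donor Treg libraries and 26.5 and 28.6 in the donor Tconv libraries. Other T cell lists had higher shares too: pan-T and CD4 lineage regions numbered 41.6 and 40.4 against 33.4 and 36.2, anergy and exhaustion 35.2 and 35.3 against 28.2 and 29.1, and TCR activation 33.9 and 34.4 against 28.6 and 28.8. The naive and quiescence list had lower ones, 57.6 and 60.8 against 64.2 and 68.3. These shares were not tested. They are divided by 31273 and 33398 regions in donor Treg but 46441 and 43345 in donor Tconv. A shorter list can thus raise a share without more regions at the listed genes. The TGF-beta list stood at the threshold (15 and 24, random net -32.8, permutation test, adjusted p = 0.049), and without the genes it shares with the Treg core list, also chosen after seeing the data, its permutation p was 0.22. The TGF-beta list was no longer past the threshold when donor Tconv replicate 1, either donor Treg library, host pTreg replicate 1 or either host tTreg library was left out of the tests. The naive and quiescence list had 9 and 92, a net of -83 against -65.5 (permutation test, adjusted p = 0.42). The lists of Th1 and cytotoxic (4 and 24), Th2 (3 and 4), Th17 (5 and 12), Tfh (4 and 17), anergy and exhaustion (3 and 15), TCR activation (7 and 19), bone marrow homing (6 and 11) and pan-T and CD4 lineage genes (5 and 24) did not pass the threshold. Nor did those of CD8 T cells (0 and 12), NK cells (2 and 7), B cells (1 and 7), plasma cells (1 and 6), myeloid cells (1 and 12), erythroid cells (2 and 2) and stem cells (3 and 8). With equal list lengths the TGF-beta call was lost (permutation test, adjusted p = 0.24), and the B cell list passed in the other direction (net 5, adjusted p = 0.046).

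In all, 1230 regions had a peak in donor Treg only and 10132 in donor Tconv only. The 11362 differing regions compare with 256 and 344 in the other splits of the 4 libraries, so more regions followed the groups than either other split. Those splits do not hold all disagreement of replicates, which shared 41400 of 48386 regions in donor Tconv and 29531 of 35140 in donor Treg. The direction of the total cannot be told apart from list length. With equal list lengths 2742 and 3307 regions differed, and the donor Treg share went from 10.8% to 45.3%. Lists of equal length bring both counts close whatever the cause, so this change does not show where the direction came from. Without donor Treg replicate 1 the donor Treg count was 2138; with a single library left in a group such counts rise by construction.

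**Figure D2:**
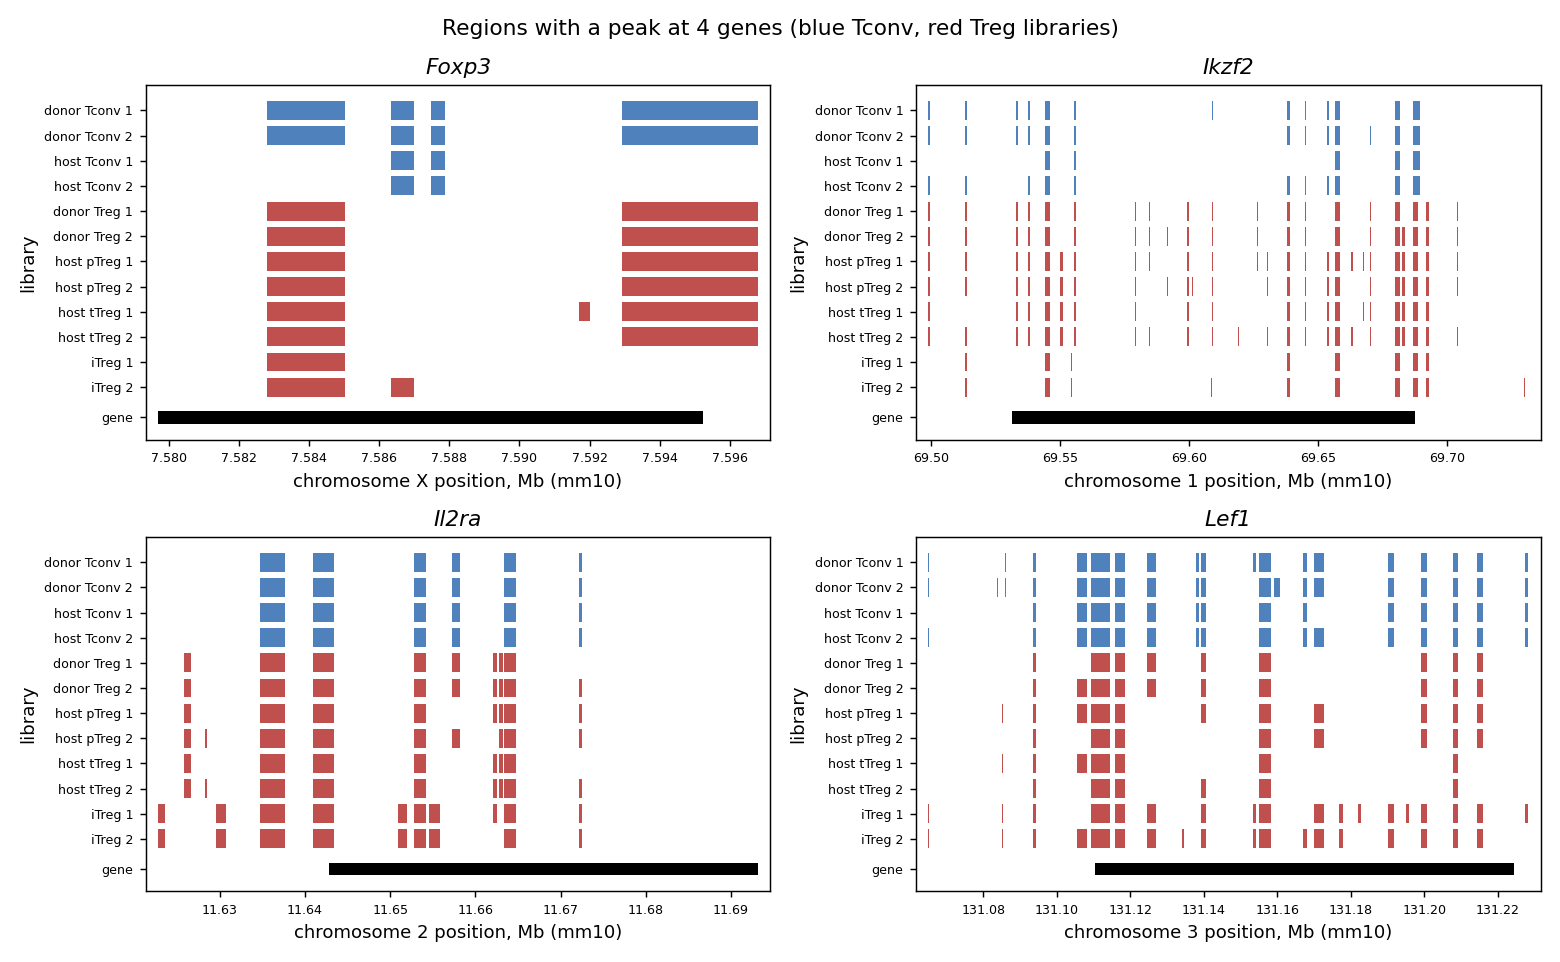
Regions with a peak at Foxp3, Ikzf2, Il2ra and Lef1 in each of the 12 libraries (rows) along the chromosome in Mb (mm10), with conventional libraries in blue, regulatory libraries in red and the gene body in black. At Foxp3 both donor Tconv libraries carry the regions at 7582796 and 7592924 that neither host Tconv library carries.

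Foxp3, the lineage factor gene of regulatory T cells (chromosome X, 7579676 to 7595243), had 5 regions inside or across the gene body, 1 of them in a single host tTreg library. The region from 7582796 to 7585032 had a peak in all 8 regulatory libraries and both donor Tconv libraries, and in neither host Tconv library. That from 7592924 to 7596817 had one in all in vivo regulatory and donor Tconv libraries, and in neither host Tconv nor iTreg library. That from 7587485 to 7587871 had a peak in all 4 conventional libraries and no regulatory library (Fisher's exact test, adjusted p = 0.032). Both Foxp3 regions that separated donor Treg from donor Tconv were therefore donor Tconv regions. The Fisher's exact call comes from the comparison over all libraries given below, where calls fell to 0 when most single libraries were left out.

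Unconverted donor and host conventional cells, both CD25 negative, were also compared. Besides origin they differ in the transgenic receptor, the transfer and list length, which cannot be told apart here. Donor Tconv had 2 Foxp3 regions that host Tconv lacked, 2 at Tbx21 and 2 at Maf, with none in reverse. Ctla4, Ikzf2, Lef1 and Lag3 had 1 and 0 each, and Nrp1 0 and 1. The leading genes in donor Tconv were Ctnnd2 and Xpo6 (5 and 0 each), Nav1, Runx2, Ankrd55 and Asap1 (4 and 0 each), and A530021J07Rik, Rbms3, Cdh13 and Klrk1, the gene of the NKG2D receptor (3 and 0 each). Host Tconv led at Tor1aip2 (0 and 3), Cyth1 (1 and 4), and Ren1, Fam163a, Tdrd5, Zp3r, Sp2, Agtpbp1, Rybp and Zfp710 (0 and 2 each). Of these leading genes, Tor1aip2, Ren1, Fam163a, Tdrd5 and Zp3r in host Tconv and Nav1 in donor Tconv lie close together. They fall in the stretch of chromosome 1 around Ptprc that is described in the last part. None of the lists passed the threshold; the Treg core list had 9 and 1 regions and the B cell list 5 and 0 (permutation test, adjusted p = 0.092).

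Here 2242 regions had a peak in donor Tconv only and 284 in host Tconv only, 2526 together against 670 and 1675 in the other splits. With equal list lengths the counts were 833 and 667, 1500 together against 536 and 797. The donor Tconv count was 3369 without donor Tconv replicate 1, 5025 without replicate 2 and 7366 without host Tconv replicate 2. The host Tconv count was 814 and 485 without donor Tconv replicates 1 and 2, and 2221 and 642 without host Tconv replicates 1 and 2.

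Converted donor cells were also compared with host Tconv. Hdac9 had 11 regions in donor Treg and none in host Tconv, Ikzf2 9 and 1, Atxn1 8 and 0, and Emsy, Cwc27 and Lamc1 6 and 0 each. Rad51b had 9 and 3, and Ceacam15, Thsd7b and Plcl1 5 and 0 each. Thsd7b and Lamc1, which also led against donor Tconv, lie in the stretch of chromosome 1 around Ptprc. Il2ra, Lrrc32 and Itgae had 3 and 0 each. Foxp3 had 2 regions in each direction, Ctla4, Nrp1 and Icos had 2 and 1 each, Ikzf4, Ccr7, Pdcd1 and Maf 1 and 0 each, and Tgfb1 0 and 1. Host Tconv led at Foxp1 (4 and 19), Cox10 (0 and 12), Zbtb16, Khdrbs3, Mbnl2, Zfp704, Snx29 and Tgfbr3 (0 and 10 each), and Myo10 and Thada (0 and 9 each), and had 9 regions at Bach2 against 2, and 4 at Lef1 and 4 at Satb1 against 0. Tcf7 and Prdm1 had 1 region in each direction.

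The Treg core list had 35 regions in donor Treg only and 10 in host Tconv only (net 25 against -17.3 in random lists), and the effector and tissue Treg list 30 and 9 (net 21 against -16.1), each with a permutation adjusted p of 0.00051. The naive list had 10 and 62 (permutation test, adjusted p = 0.86). In all 2031 regions were in donor Treg only and 6222 in host Tconv only, 8253 together against 773 and 463 in the other splits. With equal list lengths they numbered 2963 and 3081, and the donor Treg share went from 24.6% to 49%. The donor Treg count was 3276 without donor Treg replicate 1 and 3556 without host Tconv replicate 2, and the host Tconv count was 12725 without host Tconv replicate 1.

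Host regulatory cells without and with Nrp1 were not separated beyond the other splits of their libraries when all peaks were used. Regions in both host pTreg and neither host tTreg library lay at Zbtb16, which encodes the innate-like T cell factor PLZF (5 and 0), Zbtb38, St6gal1 and Wwox (4 and 0 each), and Adrb1, Mctp2, Farp1, Satb1, Nod1 and Ppp1r13b (3 and 0 each). Host tTreg had 2 and pTreg 0 at Twist2, Cpox and Nck2, and 1 and 0 at Cacnb2, Dio3, Edar, Efcc1, Fetub, Grrp1 and Gsdma. Lef1 had 3 and 0, with a net of 2 and 1 in the other splits, and Prdm1 and Icos had 1 and 0 each. Foxp3 and Ikzf2 had 0 and 0. The naive list had 12 and 2 regions (permutation test, adjusted p = 0.68) and the Treg core list 1 and 0 (adjusted p = 0.49). The 1541 differing regions, 1358 in host pTreg and 183 in host tTreg, lay between the 630 and 2150 of the other splits. With equal list lengths 775 and 566 differed, 1341 together against 747 and 806. The host pTreg count was 4765 without host pTreg replicate 2 and 4792 without host tTreg replicate 2. The host tTreg count was 841 and 315 without host pTreg replicates 1 and 2, and 2503 and 344 without host tTreg replicates 1 and 2.

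Donor Treg were set beside host pTreg and tTreg, which carry another run code, so the run and the group cannot be told apart. Against host pTreg, donor Treg led at Hdac9 (7 and 0), Emsy (5 and 0), Rad51b (5 and 1), Arpp21, Chst11, Trpm1, Baz2b and Stk39 (3 and 0 each), and Aldh1a2 and Iftap (2 and 0 each). Host pTreg led at Zbtb16 (0 and 5), Trpm2, Aopep, Nfia, Atp10a, Rapgef1, Mbnl1 and Akap13 (0 and 4 each), and Cd200r4 and Unc79 (0 and 3 each). Ikzf2 had 0 and 3, Tbx21 0 and 2, Ctla4, Tnfrsf18, Tgfb1, Prdm1 and Icos 0 and 1 each, Lrrc32, Itgae, Tcf7 and Satb1 1 and 0 each, and Bach2 2 and 1. Against host tTreg, donor Treg led at Zfand3 and Lpp (5 and 0 each), Tgfbr3 and Satb1 (4 and 0 each), and Tob1, Dyrk2, Trp53rkb, Arpp21, Cux1 and Chst11 (3 and 0 each). Host tTreg led at Spata13 (0 and 3) and Lilr4b, Ctsh, Lyn, Unc79, Hspa12a, Ncoa1, Rac2, Enthd1 and Chn2 (0 and 2 each). Lef1 had 3 and 0, Il2ra, Lrrc32, Itgae and Prdm1 1 and 0 each, Ikzf2 and Bach2 1 and 2 each, and Ctla4, Tnfrsf18 and Tgfb1 0 and 1 each. No list passed the threshold in either comparison, but in lists of equal length the naive list did against host tTreg (net 16, permutation test, adjusted p = 0.018).

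Against host pTreg, 849 regions were in donor Treg only and 1764 in host pTreg only, 2613 together against 636 and 1124 in the other splits; with equal list lengths the donor Treg share went from 32.5% to 48.8%. Against host tTreg, 1387 and 549 differed, 1936 together against 1357 and 764, and the share went from 71.6% to 56.7%. Beside host pTreg the donor Treg count was 2236 and 1456 without donor Treg replicates 1 and 2 and 2528 without host pTreg replicate 1, and the host pTreg count was 3041 without donor Treg replicate 2 and 4917 without host pTreg replicate 2. Beside host tTreg the donor Treg count was 3213 and 2155 without donor Treg replicates 1 and 2 and 4414 without host tTreg replicate 2, and the host tTreg count was 833 and 1159 without donor Treg replicates 1 and 2 and 3861 without host tTreg replicate 1.

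**Figure D3:**
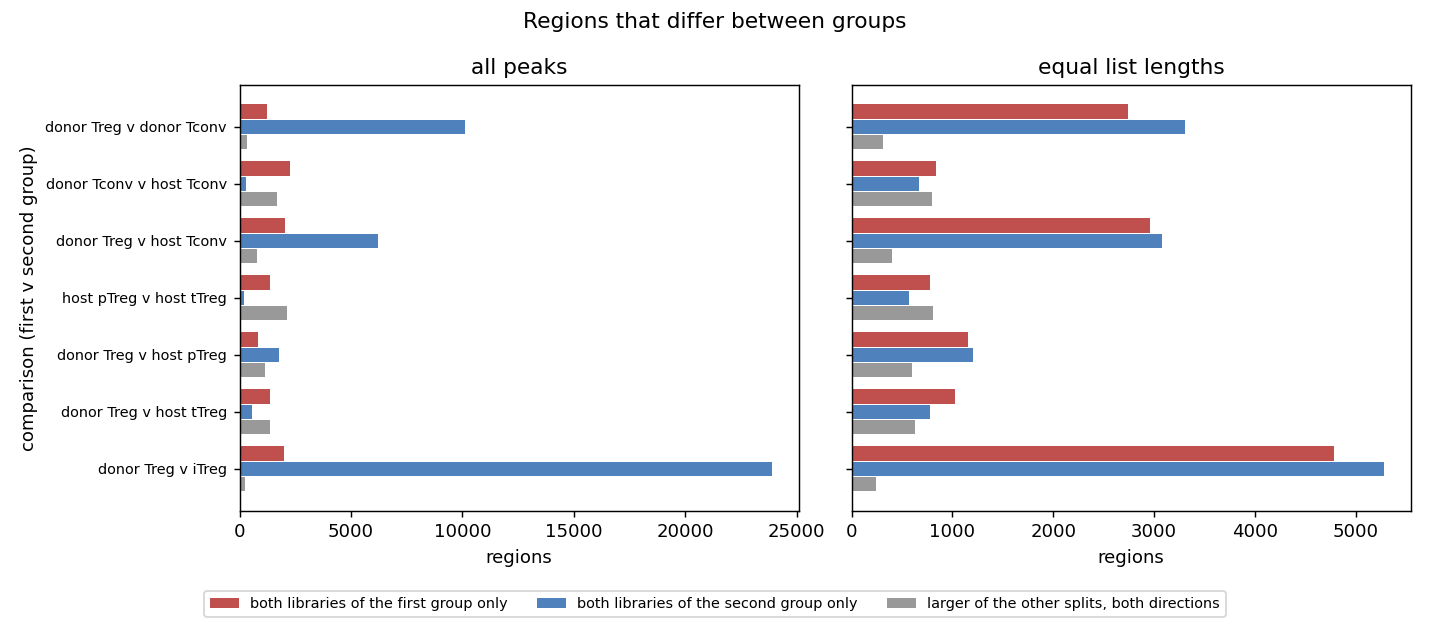
Number of regions (horizontal axis) with a peak in both libraries of one group and neither of the other, for 7 comparisons (vertical axis), with all peaks and with equal list lengths; grey bars give the larger of the other splits of the same 4 libraries. Host pTreg and tTreg differed at 1541 regions in the real split and at 2150 in another split.

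The iTreg libraries stood furthest from donor Treg, with culture and run confounded. Donor Treg led at Ikzf2 (12 and 2), Hdac9 (9 and 2), Sh3rf1 (8 and 1), Plcb4 (7 and 1), Atxn1 (7 and 2), Klrg1 (5 and 1), Arid5b (5 and 1), Tenm4 (4 and 0), Tox (9 and 5) and Med30 (3 and 0). iTreg led at Cdkal1 (0 and 23), Slc39a11 (0 and 22), Nfia (1 and 22), Maml2 (1 and 21), Elmo1 and Pard3 (0 and 20 each), Sorcs2 and Gse1 (0 and 19 each), Maml3 (1 and 19) and Tnr (0 and 17), and at Bach2 (2 and 16). Itgae had 4 and 1, Maf 2 and 0, Icos 2 and 1, and Foxp3, Ikzf4 and Pdcd1 1 and 0 each. Lef1 had 0 and 6, Satb1 0 and 5, Gata3 0 and 2, Tbx21 and Prdm1 1 and 2 each, Ctla4 4 and 5, Il2ra and Nrp1 3 and 4 each, and Tnfrsf18 and Tgfb1 0 and 1 each. Of the lists, 6 lay above matched random lists: Treg core (41 and 36, random net -60.2) and pan-T and CD4 lineage (17 and 29, -59.9), each with a permutation adjusted p of 0.00051, anergy and exhaustion (17 and 19, adjusted p = 0.00087), effector and tissue Treg (30 and 41, 0.0019), bone marrow homing (12 and 20, 0.0057) and TGF-beta (18 and 37, 0.0088). None of the 6 passed with equal list lengths (Treg core list, permutation test, adjusted p = 0.063). In all 2015 and 23891 regions differed, against 242 and 170 together in the other splits, and with equal list lengths 4786 and 5279.

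Over all libraries, 263 regions were called more often open in the 8 regulatory and 941 in the 4 conventional libraries, of 18887 tested (Fisher's exact test). All had a peak in every library of one kind and in none of the other, which gives an exact p of 0.00202, the smallest possible; 587 and 2288 had an unadjusted p under 0.05. Phlpp1 and Rora had 3 such regions each in regulatory libraries, and Nr5a2, Dgat2, Dscam, Gm46963, Ceacam15, Plcl1, Myo3b and Samsn1 had 2 each. Khdrbs3 had 6 in conventional libraries, Gab3, Pcca, Baz2b, Filip1l, Cox10, Sipa1l1, Foxp1 and Bcl2, the gene of a survival factor, 3 each, and Acadm 2. Ikzf2 had 1 in each direction, and Foxp3, Tgfb1, Lef1 and Bach2 had 1 in conventional libraries. The naive list had 0 and 12 called regions, 2 and 24 adjusted over the list alone, and no list passed (permutation test, adjusted p = 0.31 for the naive list). In lists of equal length 296 and 828 regions were called, and the Th17 list passed (net 4, permutation test, adjusted p = 0.046). Among the BW13 libraries alone, where no test was run, 1122 regions were in every regulatory and no conventional library and 5440 the reverse, which became 2170 and 2254 with equal list lengths. Fisher's exact test called 0 regions when all regions in at least 2 libraries were tested, 0 with the replicate number as a block, and 0 when either donor Tconv, donor Treg, host pTreg or host tTreg library or host Tconv replicate 2 was left out. Calls remained without iTreg replicate 1 (283 and 1031), iTreg replicate 2 (269 and 1209) or host Tconv replicate 1 (269 and 1520), and without both iTreg libraries (587 and 3770). Regions in all libraries of one kind and none of the other numbered 263 to 356 and 945 to 1520 with a library left out. The groups of a kind are not independent libraries.

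Regions of the host and cultured regulatory groups were followed into converted donor cells and into conventional cells of the same run code. Relative to all regions, the 1526 regions open in all host Treg and no iTreg library were 2.02 ± 0.047 (SD, n = 2) times as frequent in donor Treg and 0.95 ± 0.11 (n = 4) in Tconv libraries in an exact permutation test with p = 0.0667. Regions of host tTreg only gave 1.22 ± 0.035 and 0.674 ± 0.075, those of host pTreg only 0.921 ± 0.12 and 1.3 ± 0.039, and those of iTreg only 0.0865 ± 0.025 and 0.487 ± 0.077. The host tTreg set (183 regions) and the host pTreg set (1358) come from a split with fewer regions than another split of the same libraries, 1541 against 2150. They are therefore weak marks of these groups, and do not say which host group donor Treg are closer to. Regions of all host Treg gave 2.32 ± 0.091 and 1.71 ± 0.16, and those of all host Treg and both iTreg libraries 2.34 ± 0.095 and 1.76 ± 0.17. In these last sets the shares themselves were near the ceiling, 96.8% and 97.8% in donor Treg against 89.7% to 95.4% in Tconv libraries, and 97.8% and 98.6% against 93.6% to 97.8%, so the relative values differ mostly by list length. Each exact permutation p was 0.0667, the smallest that 2 against 4 libraries allow, so none can pass 0.05. With equal list lengths the 3450 regions in all host Treg and no iTreg library gave 1.43 and 0.819, those of all host Treg 1.57 and 1.41, and those of all host Treg and both iTreg libraries 1.6 and 1.54.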

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

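The B cell list was the only one of 19 whose regulatory minus conventional difference went opposite ways in every donor and every host library. Per 10000 regions with a peak, donor Treg libraries had 4.48 and 3.89 against 5.38 and 4.84 in donor Tconv, while the host regulatory libraries had 4.35 to 5.5 against 2.8 and 3.88 in host Tconv, a difference between the differences of -2.46. The difference was not tested, rests on 55 regions, and the sorts required CD4. Host regulatory and host Tconv libraries also differ in run code (DR31 and BW13), while all donor libraries are BW13. The opposite directions thus cannot be told apart from the run. With equal list lengths the B cell list lay on the other side in donor cells, 5 net regions in donor Treg against -0.0198 in random lists (permutation test, adjusted p = 0.046).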

How the results depend on the processing

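Equal list lengths, the block by R number, the Treg core list without sorted genes, the TGF-beta list without genes of the Treg core list (permutation p = 0.22), leaving out the chromosome 1 stretch, and leave-one-out of the lists and of the followed regions were chosen only after results were seen. Equal lengths replaced a planned ranking by score, which is constant; the planned motif alternatives were not run, and gene ends stood in for transcription starts.

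List length moved most counts. With equal lengths donor Treg and donor Tconv differed at 2742 and 3307 regions, donor and host Tconv at 833 and 667, donor Treg and host Tconv at 2963 and 3081, host pTreg and tTreg at 775 and 566, and donor Treg and iTreg at 4786 and 5279. Tests of lists past the threshold numbered 7 with equal lengths, 12 by the nearest gene end only, 19 without matching on regions per gene and 10 to 12 when a library was left out, against 11. The Treg core and effector Treg results against both conventional groups held in every repeat, while the TGF-beta result against donor Tconv and all 6 against iTreg were lost with equal lengths. Equal lengths added the B cell list for donor Treg against donor Tconv, the naive list for donor Treg against host tTreg and the Th17 list for regulatory against conventional libraries.

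When libraries were left out in turn, donor Treg and donor Tconv differed at 1475 to 2138 and 11283 to 14289 regions, donor and host Tconv at 2638 to 7366 and 485 to 2221, and donor Treg and host Tconv at 2184 to 3556 and 6965 to 12725. Host pTreg and tTreg gave 1632 to 4792 and 315 to 2503, donor Treg and host pTreg 1089 to 2528 and 2342 to 4917, donor Treg and host tTreg 1658 to 4414 and 787 to 3861. The same-group Jaccard mean was 0.754 in base pairs (exact permutation p = 0.111) and 0.799 to 0.821 when a library was left out, where the exact p ran from 0.0222 to 0.133. The 6 sets of regions followed into donor Treg kept their direction with equal lengths, over 1 kb from gene ends and with a library left out. That says little for all host Treg and for all host Treg and both iTreg. Their shares with all peaks are near the ceiling in every library, so the differences come mostly with list length. For all host Treg the difference went from 0.608 to 0.157 with equal lengths, for all host Treg without iTreg from 1.07 to 0.616, and for all host Treg and both iTreg from 0.574 to 0.0633.

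For regulatory against conventional libraries, pairing by replicate number as a block gave 0 regions in each direction, as did a block by R number (0 and 0) and testing all regions in at least 2 libraries (0 and 0). Replicate differences of 15 pairs of groups, by the replicate numbers of the titles, correlated at -0.13 to 0.057 and so gave no sign of pairing. These differences also carry list length, and the R numbers were not examined this way, so shared animals or days are not excluded. Without iTreg the counts were 587 and 3770, and with a library left out 0 to 283 and 0 to 1520. The counts without iTreg replicate 1 were 283 and 1031 at the same smallest possible p that gave 0 calls without any one in vivo regulatory library, and regions in all of one kind and none of the other numbered 263 to 356 and 945 to 1520 with a library left out, against 263 and 941.

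Net regions of some genes turned direction. With equal lengths these were, for donor Treg against donor Tconv, Ctla4 (3), Tbx21 (1) and Lag3 (1); for donor against host Tconv, Zfp710 (1); for host pTreg against tTreg, Icos (-1); for donor Treg against host pTreg, Icos (1), against host tTreg, Bach2 (1), and against iTreg, Ctla4 (3), Nrp1 (5) and Tbx21 (2). In fixed windows they were Ccr7 against donor Tconv (-1) and host Tconv (-1) and Bach2 against host tTreg (3). With libraries left out, Rybp between donor and host Tconv ran from -2 to 2, Icos against host Tconv from -1 to 2, Ikzf2 from -4 to 1 and Bach2 from -2 to 5 against host tTreg, and Nrp1 from -2 to 1 and Pdcd1 from -1 to 2 against iTreg.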

Other observations

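Open regions at antigen receptor variable segments were counted after values had been seen, and no test was run. Between 52427967 and 53977678 on chromosome 14, which holds the T cell receptor alpha V segments, donor Tconv libraries had 53 and 45 regions with a peak, host Tconv 33 and 39, iTreg 36 and 40, donor Treg 13 and 14, host pTreg 17 and 10 and host tTreg 4 and 11. The receptor beta V segments (chromosome 6, 40891296 to 41558371) had 32 and 27, 20 and 27, 29 and 30, 20 and 21, 21 and 18 and 14 and 21 in the same order, and the immunoglobulin heavy chain V segments (chromosome 12, 113572929 to 116009954) 48 and 40, 21 and 33, 42 and 51, 18 and 22, 37 and 24 and 13 and 19, so the 3 loci did not order the groups alike. These counts also carry list length, as libraries held from 26980 to 62670 regions with a peak. Of the regions in host pTreg and not host tTreg, 78.8% and 76.4% had a peak in the donor Tconv libraries and 58.5% and 73.6% in host Tconv, against 33.9% and 43.8% in donor Treg. Relative to all regions of a library, these were 1.3 and 1.36 in donor Tconv, 1.26 and 1.29 in host Tconv and 0.833 and 1.01 in donor Treg.

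The tests in the rest of this part were chosen after the results were seen, except that of the Treg core list in donor Tconv. Chance splits of the libraries were examined for the regulatory against conventional comparison: the real split gave 1204 regions, 1 of 100 splits gave as many, and the highest other split gave 0. That count decides nothing about chance, since most other splits part libraries of a group and calls stay at 0 even for a split of whole groups with 549 regions open in all of one side and none of the other. Splits of whole groups number 15, too few for a share under 0.05; by such regions the real value was 1204 and the highest other 549, for donor Tconv with iTreg.

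Regions shared by all 6 in vivo regulatory libraries were in donor Tconv and not host Tconv 300 times and the reverse 7 times, among them 2 at Foxp3 and 1 each at Ikzf2 and Cd83. With equal lengths the count was 253, with 90 in reverse and at most 86 in the other splits. As a share the 253 were 30.4% of donor Tconv regions, against 13.5% of host Tconv regions in reverse and up to 26.1% in the other splits. The count thus stayed above the other splits. Equal lengths keep the widest peaks, however, so a narrower peak reads as missing, and list length is not excluded. The stretch of chromosome 1 described below does not account for the count, which was 280 without it against at most 75 in the other splits. Treg or Treg-fated cells among the CD25 negative donor cells stay open as a candidate explanation, since 4 regions of the Treg core list were among them against 1.21 in random lists (permutation p = 0.075). A difference of the transferred cells themselves stays open as untested.

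Whether the larger number of regions in unconverted than converted donor cells comes from list length cannot be decided by equal lengths. With equal lengths converted cells held 45.3% of differing regions, against 10.8% with all peaks. Lists of the same length bring the counts of both groups close to each other whatever the cause. In every comparison of 2 groups the share of the first group then lay between 45.3% and 57.8%. List length stays open. A real loss of open regions on conversion is not excluded, since a longer list can itself be biological.

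Regions differing between donor and host Tconv crowded around Ptprc (138062859 to 138175756), which encodes the CD45 marker that tells donor from host: 109 of 995 (11%) in a stretch of chromosome 1 where they ran from 128742112 to 164976340 (mm10), in and out of gene bodies, against 4.84% elsewhere, rank 2 of 349 windows of that length. The edges of the stretch were chosen after seeing the data. Strain variants carried with the CD45 allele were a candidate explanation and failed the bound set for them: between donor Treg and host Tconv the share inside was 1.2 times that elsewhere, where at least 1.5 was required (1.02 between donor Treg and donor Tconv), though by side it was 1.87 for donor Treg regions and 0.98 for host Tconv regions. As 16.9% of regions elsewhere differed there, that ratio is diluted, so the regions themselves were followed in tests added after that bound had failed. Donor Tconv regions inside were in both donor Treg libraries in 29 of 79 cases against 474 of 2163 elsewhere (Fisher's exact test, p = 0.0036). Shares were also higher inside for both libraries of host pTreg (34.2% against 25.1%), host tTreg (29.1% against 18.2%) and iTreg (63.3% against 54.2%). Those shares were not tested or compared with that of donor Treg, so whether the excess is particular to donor cells stays open. Host Tconv regions were in both host pTreg libraries in 1 of 30 against 27 of 254 (Fisher's exact test, p = 0.33). The regions therefore leave variants neither shown nor excluded. List length stays open: with equal lengths differing regions were 1.97 times as frequent inside (2.26 with all peaks), against 1.55 and 1.17 in the other splits, with 1.87 for donor Tconv regions (1.83 with all peaks) and 2.1 for host Tconv regions (5.93), against up to 1.68 for one side of the other splits.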
